A study of Homo sapiens with 36 samples.

How the data were processed

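Immune cells were sorted on CD45, a surface protein of white blood cells, from basal cell carcinoma (BCC) and cutaneous squamous cell carcinoma (SCC) tumours that had been dissociated to single cells. The 36 libraries came from 30 donors who were immunocompetent (IC) or immunosuppressed (IS), and were made with the 10x Genomics 5′ chemistry, which counts polyadenylated RNA molecules per cell by unique molecular identifiers (UMIs). Per the labels, the authors ran Cell Ranger 7.1.0 against GRCh38; per the file headers, Cell Ranger was 7.1.0 for the libraries of cohort 1 and 7.2.0 for those of cohort 2. The deposited matrices hold counts, as whole-number UMI counts per gene and cell barcode, with no normalization, and list only barcodes the authors kept as cells. The other deposited files hold no measurement but the barcode and gene names of the matrices. No cell annotation was used here, and neither the intron setting nor any step against free RNA or doublets is stated.

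Library totals ran from 10835908 to 65842807 UMIs, with 2085 to 23375 barcodes per library and a median of 1164 to 5239 UMIs per barcode. All matrices list the same 36601 genes, of which 34616 were found by Ensembl ID in the GENCODE 29 annotation of GRCh38 that gave the coordinates. A comparison of each pair of libraries within a group for duplicated content found 0 identical pairs. Pairs across groups were not compared.

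The groups, the comparisons, the gene lists, the cell type markers and most alternatives were fixed before the data were examined. Groups combine tumour type and immune status, as the labels give them. Donors are the unit of replication, so libraries of the same donor were summed. Cohort 1 holds all IC donors with 4 IS_BCC and 4 IS_SCC donors, and cohort 2 holds IS donors only. With a cohort term in the model, the comparison of IS with IC therefore rests on cohort 1, while cohort 2 adds to the estimate of the spread and to the comparison of tumour types.

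Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs, which 260126 of 265761 (97.88%) met. Doublets were scored in each library by the scheme of Scrublet, against simulated pairs of its own barcodes, and the top 0.4% per 1000 barcodes was removed, 10734 in all or 0.83% to 9.35% of a library. This left 249392 cells. Up to 1200 cells per library were drawn, their counts scaled to 10000 per cell and transformed as log(1 + x). Clusters were found from 2000 genes variable within libraries, 30 principal components, a graph of shared neighbours among 20 nearest cells and the Leiden algorithm at resolution 1. Receptor and antibody segment genes, mitochondrial, ribosomal, haemoglobin, HLA and sex-linked marker genes took no part. T and NK cells, myeloid cells and B lineage cells were then clustered again with 25 components, from 1000, 800 and 600 cells per library. Cells outside the draw joined the cluster of most of their 15 nearest drawn cells. No donor integration was used, since it can remove differences between groups.

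Clusters were named by their leading genes and the fixed markers. Of 56 clusters, 34 fell into 10 classes: macrophages with monocytes (Macrophage), conventional dendritic cells (cDC), plasmacytoid dendritic cells (pDC), mast cells (Mast), CD8 T cells (CD8_T), other CD4 T cells (CD4_T), regulatory T cells (Treg), natural killer cells (NK), B cells (B) and plasma cells (Plasma). Another 13 clusters (54996 cells, cycling ones included) stayed unnamed because no class's markers led them, UMI counts were low or 2 classes' markers were mixed. Some Macrophage clusters were led by no class's markers either. Clusters with over 60% of cells in 1 library (8 with 14960 cells) were left out, as were 544 fibroblast-like cells. The classes held 178892 cells.

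Counts were summed per donor and class, and a donor entered a class with at least 20 cells of it. A class was tested if at least 3 cohort 1 donors of each group entered. This admitted Macrophage, cDC, CD8_T, CD4_T and Treg with 30 donors each, NK with 29 and Mast with 28, and left out B (2 IS_BCC donors of cohort 1), Plasma and pDC. Genes passed the count filter of edgeR (filterByExpr), were scaled by TMM and were tested by the quasi-likelihood test of edgeR with all 4 groups and the cohort in the fit. The comparisons were IS against IC (the mean of both tumour types), IS against IC within each tumour type, the difference between these effects, and SCC against BCC (the mean of both immune states). P-values were adjusted by the Benjamini-Hochberg method over the genes of a class, with a threshold of 0.05. Errors of log2 fold changes are standard errors from the model's F statistic.

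The text names genes by a rule. In macrophages these are the 12 genes of smallest p in each direction past the threshold with a log2 fold change of at least 1, for IS against IC, and elsewhere 5. Where fewer than 3 pass, the rule takes those past the threshold at any size and then the 3 of smallest p, given as not passing. Key genes of macrophages and of T and NK cells are named in any case. A few genes that the rule names are not given. X-inactivation escape genes, receptor segments and clone-named loci are left out, and sex-linked marker genes are in no table.

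Of 33 fixed gene lists, those with enough measured members in a class were tested by camera (limma) with a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data, with fry beside it; adjustment was over the lists tested in that class. Ambient lists hold transcripts of other cell types, such as keratinocytes, whose free RNA could enter the droplets. Another 3 lists were chosen after seeing the data: nuclear respiratory-chain subunits, calcineurin-NFAT targets without immediate-early genes, and heat-shock genes of the stress list. They were adjusted over classes, not lists. Shares of a class among a donor's cells in the 10 classes were compared by 2-sided tests. For IS against IC this was an exact permutation test over all 34650 splits of the cohort 1 donors within tumour type, and for SCC against BCC a permutation test with 100000 resamples within immune status and cohort; adjustment was over the 10 classes.

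Alternatives were RLE scaling, the DESeq2 Wald test, no filter on low counts, no cohort term, cohort 1 alone, at least 50 cells, doublets kept, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), the largest library of each donor, the median UMI count of the class as a covariate, a marker gate on the cells and each cohort 1 donor left out in turn. For shares, a log2 scale with 0.1% added and all 30 donors were tried. Chosen after seeing the data were dropping 4 libraries with a median under 2000 UMIs, dropping clusters with over 40% of their cells in 1 library, and counting an unnamed cluster with CD8A as CD8_T. Other splits of the donors were drawn with a fixed seed, 50 per class with the real one included.

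The steps were tested on simulated data with the real means, spread and library sizes of each class. Of 100 genes simulated with a log2 fold change of 1, the steps recovered 56 to 73, and of 100 with a log2 fold change of 2, 88 to 100; 5 to 12 of 150 to 181 calls were false. Simulated genes were independent of each other and had no cohort or tumour type effect, so these rates need not hold in the real data. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2.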

Results

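Single-cell RNA profiles were collected from CD45-sorted cells of untreated non-melanoma skin tumours, to ask how immunosuppression of the patient is reflected in the immune cells of the tumour. The design crossed immune status, immunocompetent (IC) or immunosuppressed (IS), with tumour type, basal cell carcinoma (BCC) or cutaneous squamous cell carcinoma (SCC). IC_BCC had 9 libraries from 8 donors, IC_SCC 4 libraries from 4 donors, IS_BCC 9 libraries from 9 donors and IS_SCC 14 libraries from 9 donors. Libraries held between 10835908 and 65842807 UMIs. The range was 12961941 to 64771925 UMIs in IC_BCC, 20171332 to 36205347 in IC_SCC, 10835908 to 64178705 in IS_BCC and 19129548 to 65842807 in IS_SCC. The median UMI count per barcode of a library ran from 1164 to 5239, and 4 libraries (2 IC and 2 IS) had a median under 2000. Cohort 2 held IS donors only, so the comparison of IS with IC was made with a cohort term and rests on the 12 IC and 8 IS donors of cohort 1. Levels are CPM of the summed cells of a donor, given as mean ± SD over donors. Fold changes are log2 values ± SE.

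The tumours held the main immune lineages in every group. CD4 T cells other than regulatory T cells were the most numerous class with 39158 cells, followed by 35113 CD8 T cells, 31909 macrophages (monocytes included), 29958 conventional dendritic cells and 19704 regulatory T cells. Smaller classes were 9284 B cells, 6469 mast cells, 5850 natural killer (NK) cells and 915 plasma cells, counted over the donors with at least 20 cells of the class. FOXP3, the lineage factor of regulatory T cells, had a UMI in 63.88% of regulatory T cells (median depth 3221 UMIs) and in 0.31% of macrophages (median depth 6123 UMIs), which should lack it. CD14, a monocyte and macrophage receptor, had a UMI in 60.11% of macrophages and in 0.30% of CD4 T cells (median depth 3309 UMIs). TPSAB1, the gene of mast cell tryptase, had a UMI in 98.12% of mast cells at a median depth of 1322 UMIs, and also in 5.64% of macrophages. Clusters drawn mostly from 1 library took 6.26% of cells in IC_BCC, 1.76% in IC_SCC, 1.01% in IS_BCC and 9.50% in IS_SCC, as means over donors, and were left out.

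No immune class differed in its share between IS and IC tumours beyond the spread between donors. Among the 20 donors of cohort 1, macrophages made up 16.1% of the classed cells in IS and 15.8% in IC, conventional dendritic cells 15.9% and 16.1%, CD8 T cells 21% and 20.9%, CD4 T cells 22.3% and 24.9%, and regulatory T cells 12.7% and 11.5%. B cells made up 5.15% in IS and 2.95% in IC, and NK cells 2.92% and 3.87%. In the exact permutation test over 34650 splits, 2-sided, the smallest p of the 10 classes was 0.412, for B cells, and all adjusted p were 0.989. The test measured each difference from the mean over splits, because IS and IC donors differ in their mix of tumour types. So measured, it was −0.321 in macrophages and 0.694 in conventional dendritic cells, opposite in sign to the plain differences. The difference in macrophages was also small against their spread, with shares of 15.2% ± 13.0 (SD, n = 8) in IC_BCC, 17.03% ± 20.3 (n = 4) in IC_SCC, 14.1% ± 7.05 (n = 9) in IS_BCC and 25.5% ± 22.7 (n = 9) in IS_SCC, both cohorts included. Shares also depend on the dissociation and the sort. Between tumour types, macrophages made up 22.9% in SCC (13 donors) and 14.6% in BCC (17 donors), with a permutation p of 0.225, and conventional dendritic cells 14.4% and 21.5%, with a permutation p of 0.0675; the smallest adjusted p of the 10 classes was 0.649.

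**Figure D1:**
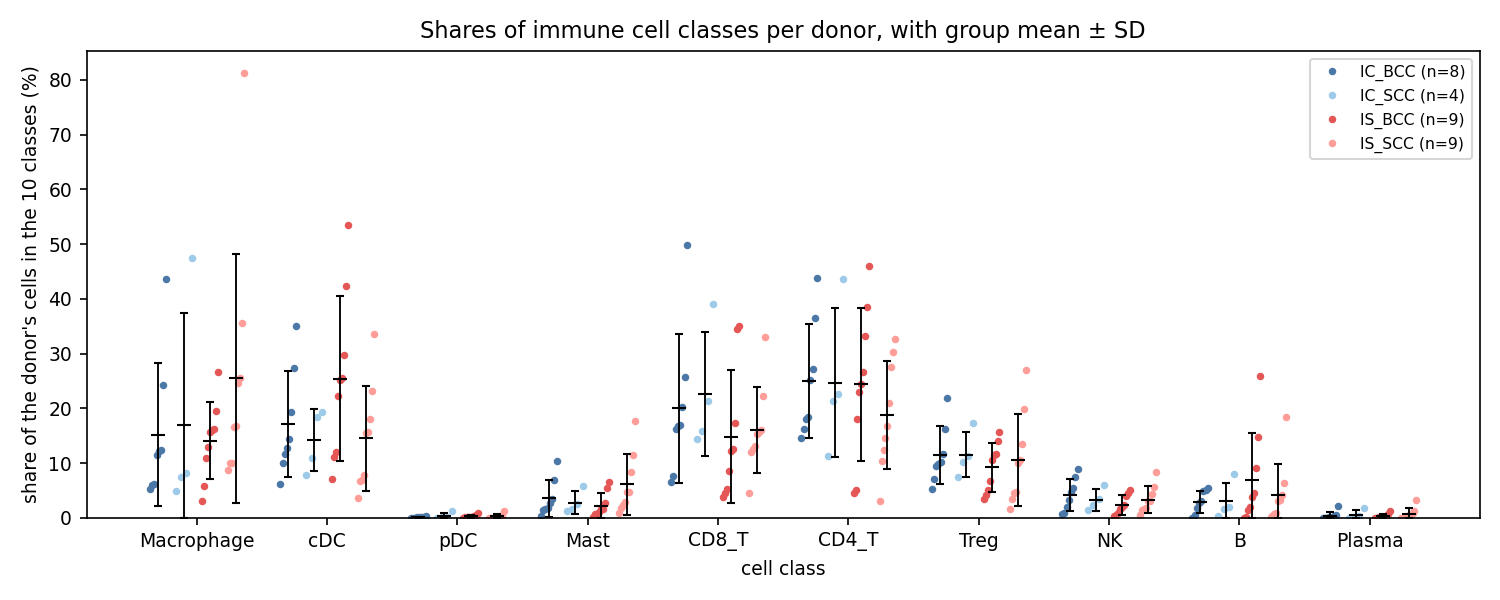
Share of each immune cell class (y axis, % of the donor's cells in the 10 classes) for the 4 groups, with 1 point per donor and the group mean ± SD as bars clipped at 0. The groups overlap in every class, and the highest macrophage share is 81.3%, in IS_SCC.

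In macrophages, the gene of smallest p between IS and IC encodes a scavenger receptor, and it missed the threshold. MARCO, a macrophage receptor that binds bacteria and modified lipids, had a log2 fold change of 2.07 ± 0.39 in IS against IC. Its level was 41.4 ± 9.03 CPM in IC_BCC (n = 8), 26.5 ± 9.43 in IC_SCC (n = 4), 84.5 ± 49.2 in IS_BCC (n = 9) and 103 ± 98.98 in IS_SCC (n = 9). It lay above the IC mean of the same tumour type, the reference for such counts throughout, in 14 of 18 IS donors and in 7 of the 8 of cohort 1. IGFBP2, which encodes a secreted binding protein of insulin-like growth factors, had 3.70 ± 0.70 at a far lower level, 1.46 ± 1.16 CPM in IC_BCC and 9.83 ± 19.1 in IS_SCC. It was above the IC mean in 8 of 18 IS donors. Both missed the threshold at an adjusted p of 0.0711. The Wald test of DESeq2 called both and no other gene (adjusted p 0.00077 for MARCO and 0.00138 for IGFBP2). MARCO (ENSG00000019169) lies on chromosome 2, 118942166 to 118994660, plus strand, and IGFBP2 (ENSG00000115457) on chromosome 2, 216632828 to 216664436, plus strand, in GRCh38. Both were highest in a macrophage cluster led by SPP1, APOE and TREM2, with 222.9 CPM of MARCO and 33.15 CPM of IGFBP2 against 14.8 to 69.4 CPM of MARCO in the other macrophage clusters. That cluster drew 44.95% of its cells from 1 library. Without the clusters that had over 40% of their cells in 1 library, the fold change of MARCO was 1.24 ± 0.311 (adjusted p 0.892).

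By edgeR, 0 of 13838 genes in macrophages passed an adjusted p of 0.05 between IS and IC, with 929 at an unadjusted p under 0.05 and 2 calls by DESeq2 (1001 at an unadjusted p under 0.05). The remaining genes of smallest p, none of which passed, were ATP5F1A, a subunit of mitochondrial ATP synthase (0.57 ± 0.14, above the IC mean in 17 of 18 IS donors), and CCSER2 (−0.63 ± 0.14, above it in 0 of 18). They also held SLCO5A1 (−1.09 ± 0.29) and USP53 (−0.87 ± 0.24, above it in 1 of 18). For SLCO5A1 the sign rests on cohort 1, where 0 of 8 IS donors were above the IC mean, against 9 of 18 over both cohorts. Key genes of macrophage states fixed in advance did not pass. Complement genes had C1QA 0.40 ± 0.25 and C1QB 0.60 ± 0.36, and genes of lipid handling and matrix had APOE 0.66 ± 0.71, TREM2 0.55 ± 0.42 and SPP1 0.40 ± 0.81. The scavenger and mannose receptors had CD163 0.31 ± 0.23 and MRC1 0.31 ± 0.32. HLA-DRA, the chain shared by all HLA-DR molecules, had −0.35 ± 0.19. Cytokines and chemokines had IL1B −0.42 ± 0.45, TNF 0.11 ± 0.51, CXCL9 −0.50 ± 0.64 and CXCL10 0.79 ± 0.63. Monocyte genes had S100A8 0.36 ± 0.52 and VCAN 0.11 ± 0.44. FKBP5 and TSC22D3, which glucocorticoids induce, had 0.39 ± 0.31 and 0.03 ± 0.28. The adjusted p of these 16 genes ran from 0.742 to 0.993.

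**Figure D2:**
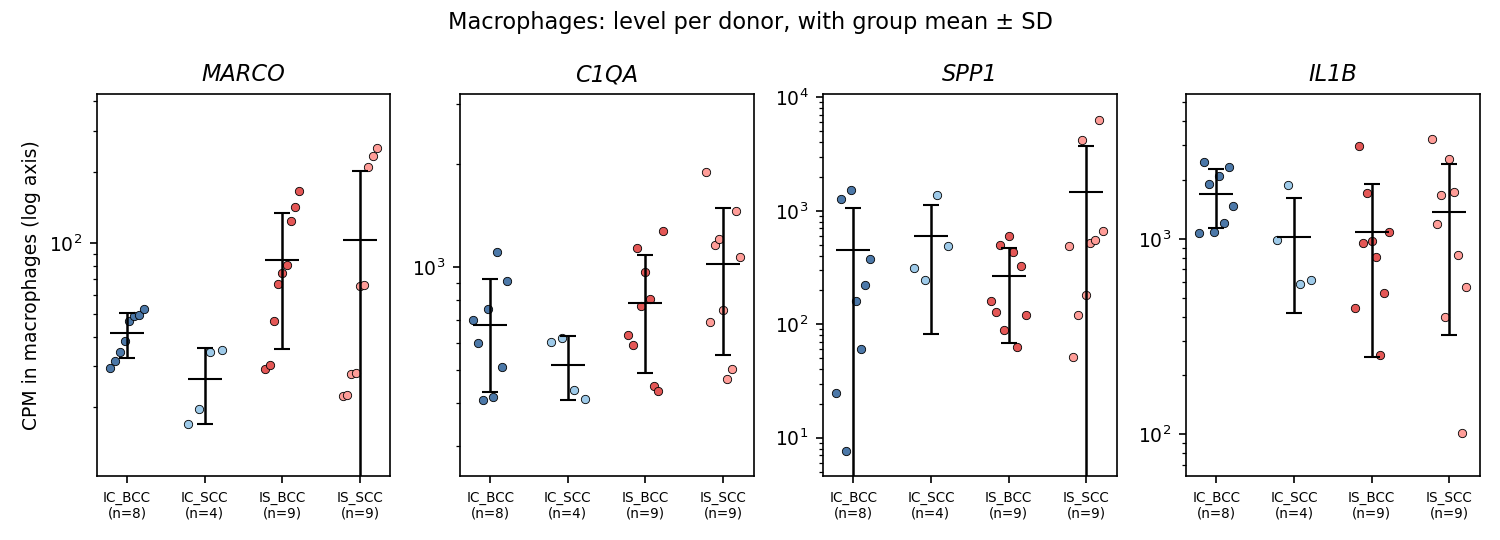
Levels of MARCO, C1QA, SPP1 and IL1B in macrophages (y axes, CPM on a log scale) by group, with 1 point per donor and the group mean ± SD as bars, clipped above 0. Mean MARCO is 41.4 and 26.5 CPM in IC_BCC and IC_SCC and 84.5 and 103 CPM in IS_BCC and IS_SCC, and donors of IC and IS overlap for each of the 4 genes.

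As groups, 3 of 23 gene lists passed between IS and IC macrophages with the preset correlation, and 0 with an estimated correlation (adjusted p 0.906 for each of the 3). The count was 9 without the cohort term, 5 without clusters over 40% in 1 library and 2 to 6 with 1 donor left out. Type I interferon response genes, which cells switch on after virus or nucleic acid sensing, had a positive fold change in 20 of 21 measured members, with a mean of 0.60, led by IFIT2 1.68 ± 0.59 and IFIT3 1.38 ± 0.61 (adjusted p 0.00164). The list of phagocytosis and Fc receptors was higher, with 17 of 21 positive and a mean of 0.24 (adjusted p 0.0213). Its leading members were MARCO and NCF1, a subunit of the phagocyte oxidase (0.67 ± 0.31), and 1 member, MARCO, passed adjusted over the list alone. The list of inflammatory cytokines and NF-kB targets was lower, with 11 of 17 negative, a median of −0.32 and a mean of −0.15 (adjusted p 0.00371), led by CXCL3 −0.62 ± 0.45 and EREG −0.73 ± 0.57. In 20 fits that each left out 1 donor, the interferon call ended once (mean 0.26 to 0.77, adjusted p up to 0.263), the phagocytosis call 3 times (0.20 to 0.35, up to 0.125) and the cytokine call 2 times (−0.43 to 0.05, up to 0.123). Without the cohort term the cytokine mean turned to 0.12 (adjusted p 0.1996). Without shallow libraries, those with a median under 2000 UMIs, the interferon call ended (0.49, 0.0780). The phagocytosis call ended in cells that passed the marker gate (0.23, 0.0501) and without clusters over 40% in 1 library (0.18, 0.0792). No member of any list passed over all genes. The lists of complement and residency (mean 0.10), lipid association (0.13), MHC class II (−0.15), interferon-gamma response (0.04), lysosome (0.03), monocyte recruitment (−0.12), matrix and angiogenesis (−0.02), checkpoint and costimulation ligands (0.05) and glucocorticoid response (0.08) did not pass. Ambient immunoglobulin transcripts had a mean of −1.89 (adjusted p 0.162), and keratinocyte transcripts −0.38 (adjusted p 0.4662). The cells of the class were not the same mixture in each group. The largest macrophage cluster was led by AQP9, CXCL2 and C5AR1 in IC (27.31% of the class in IC_BCC and 20.08% in IC_SCC), and by THBS1, EREG and HILPDA in IS (24.46% in IS_BCC and 21.75% in IS_SCC). The SPP1 and APOE cluster took 6.88% in IC_BCC, 13.53% in IC_SCC, 12.74% in IS_BCC and 21.33% in IS_SCC.

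In conventional dendritic cells, antigen presentation and inflammatory genes tended to lower values in IS tumours, a shift called with the preset correlation and lost with an estimated one. The MHC class II list was lower, with 10 of 12 members negative and a mean of −0.17 (adjusted p 0.00542, and 0.737 with an estimated correlation), led by HLA-DQA1 −0.34 ± 0.17 and HLA-DRA −0.35 ± 0.20. Inflammatory cytokines and NF-kB targets were lower in 14 of 17, mean −0.40 (adjusted p 0.00389 and 0.737), led by IL23A −1.36 ± 0.66, a chain of the cytokine IL-23, and PTGS2 −0.63 ± 0.35. Hypoxia and glycolysis genes were negative in 14 of 17, mean −0.19 (adjusted p 0.0264 and 0.737), led by PFKFB3 −0.37 ± 0.26 and VEGFA −0.51 ± 0.40. These were the 3 of 18 lists that passed with the preset correlation. Leaving out 1 donor ended the presentation call in 2 of 20 fits (−0.23 to −0.08, adjusted p up to 0.224), the cytokine call in 1 (−0.58 to −0.14, up to 0.118) and the hypoxia call in 8 (−0.38 to −0.08, up to 0.186). Without the cohort term the means were 0.09, −0.01 and 0.20, and none of the 3 passed. Without shallow libraries the hypoxia mean was 0.04 (adjusted p 0.973). Of single genes, edgeR called 0 of 15312 (821 at an unadjusted p under 0.05) and DESeq2 0 (969 at an unadjusted p under 0.05). Smallest in p, without passing, were ANKZF1 0.60 ± 0.17, TRIAP1 0.49 ± 0.14, RELN 3.53 ± 1.05, IGHA1 −5.16 ± 1.29, MIR4458HG −1.58 ± 0.43 and NEURL3 −1.62 ± 0.48. The value of IGHA1, an antibody heavy chain gene, rests on 1 IC_SCC donor: leaving out each donor in turn gave −6.09 to 0.44. The largest dendritic cluster differed too, being led by CD1C and FCER1A in IC_BCC and IS_SCC, by CCR7 and IL23A in IC_SCC and by RTN1 and CD1C in IS_BCC.

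CD8 T cells of IS tumours had higher values of interferon and cytotoxic genes as groups with the preset correlation, and no call held with an estimated one. The type I interferon list was positive in 20 of 21, mean 0.41 (adjusted p 3.87e-05, and 0.543 with an estimated correlation), led by IFIT3 1.57 ± 0.52 and IFIT2 1.28 ± 0.44. Cytotoxicity genes were positive in 14 of 17, mean 0.24 (adjusted p 0.0127 and 0.543), led by FGFBP2 1.07 ± 0.44 and GZMH 0.68 ± 0.30, a granzyme. The interferon-gamma list was positive in 11 of 11, mean 0.17 (adjusted p 0.0194 and 0.543), led by GBP1 0.39 ± 0.17 and GBP4 0.39 ± 0.20. The MHC class I list was positive in 10 of 13, mean 0.10 (adjusted p 0.0268 and 0.543), led by HLA-F 0.24 ± 0.13. Mitochondrially encoded transcripts, also a sign of cell quality, were negative in 13 of 13, mean −0.23 (adjusted p 0.00049 and 0.576), led by MT-ND6 −0.55 ± 0.24 and MT-ND2 −0.32 ± 0.19. These were 5 of 17 lists. These calls ended in 0 of 20 fits with 1 donor left out for type I interferon (mean 0.25 to 0.53), 2 for cytotoxicity (0.13 to 0.36, adjusted p up to 0.110), 6 for interferon-gamma (0.11 to 0.26, 0.173), 5 for MHC class I (0.09 to 0.13, 0.125) and 1 for the mitochondrial list (−0.30 to −0.15, 0.0607). Without the cohort term the interferon-gamma call ended (0.11, adjusted p 0.243). By edgeR 0 of 11506 genes passed (427 at an unadjusted p under 0.05), and by DESeq2 0 (551 at an unadjusted p under 0.05). Genes of smallest p, not passing, were ALKBH7 0.42 ± 0.11, HIGD2A 0.35 ± 0.10, a factor of the respiratory chain that was above the IC mean in 18 of 18 IS donors, and UBE2L6 0.51 ± 0.15. Lower ones were PLCL1 −1.46 ± 0.39 and DOCK3 −1.16 ± 0.32, both above it in 0 of 18, and BAIAP3 −1.66 ± 0.45. Effector and checkpoint genes showed IFNG 0.10 ± 0.30, GZMB 0.33 ± 0.46, PRF1 0.06 ± 0.20, PDCD1 −0.27 ± 0.24, CTLA4 −0.31 ± 0.38, and LAG3 −0.05 ± 0.24. The others had HAVCR2 −0.16 ± 0.35, TIGIT −0.39 ± 0.24, CXCL13 −0.77 ± 0.80, TCF7 −0.24 ± 0.22, IL2RA −0.35 ± 0.40 and FKBP5 0.07 ± 0.41, all at an adjusted p of 1. The largest CD8 cluster was led by IFNG, GZMK and CRTAM except in IC_SCC, where it was led by GZMK and DTHD1.

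CD4 T cells and regulatory T cells of IS tumours also had higher type I interferon genes as a group, together with more myeloid transcripts. In CD4 T cells 21 of 21 interferon genes were positive, mean 0.64 (adjusted p 1.62e-06 with the preset and 0.765 with an estimated correlation), led by IFIT2 1.96 ± 0.54 and IFIT3 1.73 ± 0.57. Adjusted over the list alone, 2 members passed. In regulatory T cells 20 of 20 were positive, mean 0.36 (adjusted p 0.00142 and 0.893), led by EPSTI1 0.49 ± 0.24 and OAS2 0.31 ± 0.17. Ambient myeloid transcripts were positive in 8 of 8 in CD4 T cells, mean 0.61 (adjusted p 0.00319 and 0.729), led by TYROBP 0.56 ± 0.30 and C1QB 0.92 ± 0.64. In regulatory T cells they were positive in 4 of 4, mean 0.77 (adjusted p 9.59e-05 and 0.0643), led by CD68 0.70 ± 0.35 and TYROBP 0.96 ± 0.49. Mitochondrially encoded transcripts were negative in 13 of 13 in regulatory T cells, mean −0.20 (adjusted p 0.00150 and 0.893), led by MT-ND6 −0.46 ± 0.27 and MT-ND2 −0.35 ± 0.20. With 1 donor left out, the interferon call of regulatory T cells ended in 2 of 20 fits (0.08 to 0.47, adjusted p up to 0.524) and their mitochondrial call in 3 (−0.28 to −0.12, up to 0.266), while the other 3 calls held in all 20, with means of 0.40 to 0.78 for interferon and 0.49 to 0.81 for myeloid transcripts in CD4 T cells and 0.65 to 1.58 for myeloid transcripts in regulatory T cells. The interferon call of regulatory T cells also ended without the cohort term (0.27, 0.5678) and without shallow libraries (0.34, 0.0686), their mitochondrial call without shallow libraries (−0.10, 0.248) and the myeloid call without the cohort term (0.59, 0.117). By edgeR 0 of 13854 genes passed in CD4 T cells (385 at an unadjusted p under 0.05) and 0 of 11350 in Treg cells (254), and by DESeq2 0 in each (506 in CD4_T and 306 in Treg at an unadjusted p under 0.05). Smallest in p in CD4 T cells were PTGR1 4.53 ± 1.12, CTSL 1.39 ± 0.36, IFIT2, SLCO5A1 −1.12 ± 0.30 and PDE3A −1.32 ± 0.40. In regulatory T cells they were SNHG20 0.96 ± 0.27, DENND6B 1.28 ± 0.37, ADA 0.77 ± 0.23, C9orf135 −4.79 ± 1.08, SLCO5A1 −1.05 ± 0.26 and GFOD1 −1.08 ± 0.27. In regulatory T cells FOXP3 had 0.12 ± 0.12, IL2RA 0.22 ± 0.20, CTLA4 −0.24 ± 0.14, TIGIT −0.22 ± 0.18, and PDCD1 −0.36 ± 0.22. Further values were LAG3 −0.36 ± 0.59, HAVCR2 0.21 ± 0.34, CXCL13 1.06 ± 0.65, TCF7 0.39 ± 0.25, IFNG 0.56 ± 0.53, GZMB 0.06 ± 0.78, PRF1 0.07 ± 0.24 and FKBP5 0.50 ± 0.38. In CD4 T cells the same genes had FOXP3 0.54 ± 0.48, IL2RA 0.23 ± 0.36, CTLA4 0.07 ± 0.32, TIGIT 0.17 ± 0.35, and PDCD1 −0.11 ± 0.28. Next to these were LAG3 0.15 ± 0.44, HAVCR2 0.17 ± 0.48, CXCL13 1.21 ± 1.03, TCF7 0.17 ± 0.26, IFNG −0.03 ± 0.47, GZMB 1.21 ± 0.78, PRF1 0.37 ± 0.41 and FKBP5 −0.16 ± 0.35. All of them had an adjusted p of 1. Treg cells held 2 clusters in like proportions except in IS_BCC, where the cluster led by MAGEH1 and LAYN took 50% against 36.3% in IC_BCC. The largest CD4 cluster was led by CD40LG and ZFP36L2 in IC, by NTRK2 and CSF2 in IS_BCC and by LEF1 and TCF7 in IS_SCC.

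NK and mast cells of IS tumours also had higher interferon genes as a group. The list was positive in 11 of 14 in NK cells, mean 0.28 (adjusted p 0.0284, and 0.930 with an estimated correlation), led by OAS3 1.03 ± 0.46 and OAS1 0.86 ± 0.44. In mast cells it was positive in 13 of 13, mean 0.93 (adjusted p 0.00076, and 0.809 with an estimated correlation), led by MX1 2.22 ± 0.75 and MX2 1.11 ± 0.42. In NK cells calcineurin-NFAT targets, the genes that ciclosporin and tacrolimus act on, were negative in 13 of 16, mean −0.40 (adjusted p 0.00917, and 0.930 with an estimated correlation), led by EGR2 −0.62 ± 0.29 and TNF −0.79 ± 0.40. With 1 donor left out, the interferon call ended in 7 of 19 fits in NK cells (0.05 to 0.40, adjusted p up to 0.367) and in 1 of 19 in mast cells (0.29 to 1.13, up to 0.607). The NFAT call of NK cells ended in 5 of 19 (−0.51 to −0.17, up to 0.281). The interferon call of NK cells also ended without the cohort term (0.21, adjusted p 0.3001), with the marker gate (0.13, 0.487) and without shallow libraries (0.19, 0.672), and that of mast cells without the cohort term (0.54, 0.177) and without shallow libraries (0.92, 0.063). The NFAT call ended without the cohort term (−0.11, 0.332) and with the marker gate (−0.43, 0.139). The NFAT list did not pass in the other classes, with adjusted p from 0.0509 in CD4 T cells to 0.820 in conventional dendritic cells. Lists of glucocorticoid response and of mTORC1 and sterol targets passed in none of the 7 classes between IS and IC. By edgeR 0 of 7808 genes passed in NK cells (223 at an unadjusted p under 0.05; DESeq2 0 and 262) and 0 of 8387 in Mast cells (357; DESeq2 0 and 413). Genes of smallest p in NK cells were NAAA 0.86 ± 0.26, TCAIM 1.03 ± 0.32, ABCA1 1.56 ± 0.51, FEZ1 −1.57 ± 0.41, P2RX5 −2.40 ± 0.63 and HIST1H1B −2.47 ± 0.75. The key genes had IFNG −0.34 ± 0.44, GZMB −0.17 ± 0.46, PRF1 −0.13 ± 0.18, LAG3 0.28 ± 0.63, HAVCR2 −0.39 ± 0.23, TIGIT −0.81 ± 0.33, TCF7 −0.23 ± 0.31, IL2RA −0.82 ± 0.42 and FKBP5 −0.06 ± 0.47. In mast cells they were RNPEP 0.97 ± 0.20 (adjusted p 0.2002), IER5 1.30 ± 0.35, DGKH 2.19 ± 0.64, BCAR1 −1.40 ± 0.34, ITGB3 −1.15 ± 0.29 and L1CAM −3.17 ± 0.80. Among the 7 classes, only conventional dendritic cells had no call for the type I interferon list (mean 0.25, adjusted p 0.119); a difference between classes was not tested.

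**Figure D3:**
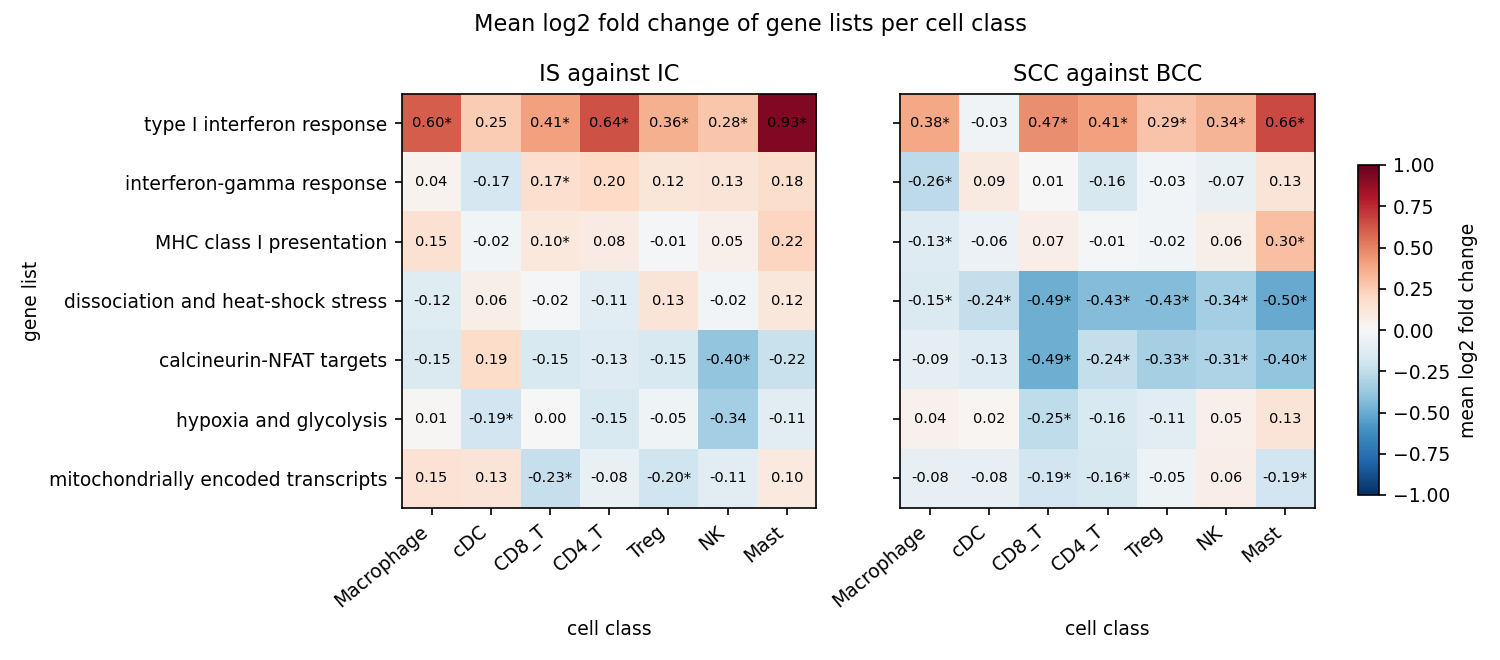
Mean log2 fold change of 7 gene lists (rows) in 7 cell classes (columns), for IS against IC and for SCC against BCC, with the value printed in each cell and an asterisk where the adjusted p of camera with the preset correlation is under 0.05. The type I interferon list is positive in 7 classes for IS against IC, up to 0.93 in mast cells, and the stress list is negative in 7 classes for SCC against BCC.

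Within tumour types, MARCO and IGFBP2 in macrophages had the same sign in BCC and in SCC, without passing by edgeR. MARCO had 1.78 ± 0.48 in BCC and 2.36 ± 0.57 in SCC, and IGFBP2 2.75 in BCC and 4.64 ± 1.11 in SCC. In SCC, mast cells had higher CTSS, a protease, at 2.55 ± 0.50 (9.90 ± 6.41 CPM in IC_SCC and 48.5 ± 29.2 in IS_SCC), and RNPEP, an aminopeptidase, at 1.52 ± 0.29, both at adjusted p 0.0610. RNA of myeloid cells is not excluded for CTSS. CD38 had 4.81 ± 1.08 (adjusted p 0.197). On chromosome 1, CTSS (ENSG00000163131) lies at 150730196 to 150765957, minus strand, and RNPEP (ENSG00000176393) at 201982372 to 202006147, plus strand. DESeq2 called both, with L1CAM (−4.64) and the clone-named AP000676.5 (−3.26).

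The same comparisons by edgeR within BCC called 0 genes in each class, with 401 at an unadjusted p under 0.05 in Macrophage, 414 in cDC, 292 in CD8_T, 199 in CD4_T, 229 in Treg, 232 in NK and 187 in Mast; DESeq2 called SLC35E2A in Treg and FAM157C in Mast. Within SCC edgeR also called 0, with 1154, 1070, 641, 688, 578, 201 and 517 at an unadjusted p under 0.05, while DESeq2 called MARCO, TMEM219, KCNH8 and ATP10B in Macrophage, HIGD2A in CD8_T, GFOD1 in Treg and the 4 genes in Mast. Under DESeq2 the counts at an unadjusted p under 0.05 were 457, 462, 343, 250, 280, 281 and 204 within BCC and 1235, 1224, 764, 829, 672, 215 and 548 within SCC, in the same order of classes.

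Within BCC the genes of smallest p, not passing, were XIRP1 4.51, DUXAP8 2.90, MARCO, SLCO5A1 −1.28, PDE3A −1.59 and LYPD3 −1.51 in macrophages, and SLC35E2A 1.06, NFXL1 1.37, DUXAP8 3.16, MIR4458HG −2.0 and XAGE1B −3.99 in dendritic cells. They were FAM89B 1.17, RPS10 1.53, DDT 0.82, DUSP16 −0.87, LATS2 −1.48 and HIPK3 −0.46 in CD8 T cells. The CD4 T cells had GATD3A 3.27, DUXAP8 2.70, SLC35E2A 0.85, TLE1 −1.60, POMC −1.25 and MT1E −3.15, and regulatory T cells SLC35E2A 1.07, DUXAP8 3.37, GRAP 1.28, C9orf135 −5.36, VWDE −2.60 and ACTG2 −2.25. NK cells had TMEM216 1.52, PAX8-AS1 2.18, TCAIM 1.42, FEZ1 −2.05, P2RX5 −2.80 and LIMD1 −0.92, and mast cells FAM157C 2.55, CAMKMT 1.04, PRKG1 −3.99, BCAR1 −1.76 and NRIP3 −2.27. Within SCC they were FIBP 0.65, IGFBP2, MARCO, ATP10B −3.03, KCNH8 −2.81 and NEBL −6.18 in macrophages, TRIAP1 0.82, BDH2 1.05, IL18 0.75, IGHA1 −8.52, GPR31 −3.83 and HPD −4.68 in dendritic cells. The CD8 T cells had HIGD2A 0.58, DNAJC4 0.72, MDH2 0.70, PLCL1 −2.11, IKZF2 −1.55 and NLRP3 −1.21. CD4 T cells had OCIAD2 0.93, CCL4L2 6.49, PTGR1 7.47, SLC39A14 −1.26 and KCNJ6 −4.29, and regulatory T cells ADA 1.45, DENND6B 2.17, CHCHD5 0.75, GFOD1 −1.81, PTCHD1 −3.55 and LHFPL6 −2.87. NK cells had FAM126A 1.07, HLA-DPB1 0.83, CHMP3 0.88, GPR107 −1.0, GNG4 −2.84 and KIF3B −1.0, and mast cells, besides those named, L1CAM −4.25, STARD10 −1.81 and ITGB3 −1.48.

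One gene passed where the effect of immune status was compared between the tumour types. In regulatory T cells SLC35E2A had a difference of −1.67 ± 0.29 (adjusted p 0.0306). It was higher in IS than in IC in BCC (8.71 ± 1.92 CPM, n = 8, and 17.8 ± 4.67, n = 9) and lower in SCC (16.9 ± 5.03, n = 4, and 10.4 ± 2.81, n = 9). SLC35E2A (ENSG00000215790, chromosome 1, 1724838 to 1745999, minus strand) has a near-identical neighbour, SLC35E2B, and reads shared between the copies cannot be placed surely. The call was kept in 10 of 20 fits that left out 1 donor each, with adjusted p from 0.0118 to 0.288. In CD4 T cells POMC, the precursor of melanocortins, had a difference of 2.76 ± 0.53 (adjusted p 0.162; called by DESeq2 at 0.0252), with 4.52 ± 1.85 CPM in IC_BCC, 2.19 ± 0.617 in IS_BCC, 2.36 ± 0.71 in IC_SCC and 7.88 ± 4.12 in IS_SCC. For this difference edgeR called 0 genes in Macrophage, cDC, CD8_T, CD4_T, NK and Mast, with 652, 630, 515, 503, 206 and 362 at an unadjusted p under 0.05, and 1 in Treg, with 658. DESeq2 called POMC, TLE1, MT1E and PBX2 in CD4_T and SLC35E2A and FAM157C in Treg, and 0 elsewhere (728 in Macrophage, 750 in cDC, 588 in CD8_T, 244 in NK and 402 in Mast at an unadjusted p under 0.05).

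Other genes of smallest p for this difference, not passing, were FIBP 0.65, TIPARP-AS1 2.09, CHMP5 0.84, APOD −4.28, SYN3 −5.16 and ATP10B −3.02 in macrophages, and MT1H 11.14, BDH2 1.21, C1orf56 1.07, PLEKHM3 −1.34, GPR31 −4.09 and GINS3 −1.97 in dendritic cells. They were CHURC1 0.86, MDH2 0.72, SELPLG 0.89, SLC35E2A −1.23, SLAMF7 −0.70 and FAM157C −2.22 in CD8 T cells. The CD4 T cells had TLE1 2.53, CCL4L2 7.78, SLC35E2A −1.33 and SLC25A29 −1.64, and regulatory T cells VWDE 4.02, MT1E 3.57, MIEN1 1.02, FAM157C −3.05 and OTUD7A −1.95. NK cells had CHSY1 1.38, FAM126A 1.37, RGS1 1.45, TMEM216 −1.80, ZC4H2 −2.22 and TTLL5 −1.23, and mast cells CTSS 2.91, PRKG1 4.67, SLC8B1 2.30, FAM157C −3.25, DHX34 −1.90 and STARD10 −1.81. Several of these, among them FAM157C, DUXAP8, GATD3A, CCL4L2, RPS10, XAGE1B, MT1E and MT1H, have close copies in the genome, so their counts depend on how shared reads were placed.

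Between tumour types, immune cells of SCC had lower immediate-early and heat-shock genes and higher interferon genes than those of BCC, with the preset correlation and not with an estimated one. The stress list, genes that handling and dissociation also raise, was negative in 16 of 16 members in dendritic cells (mean −0.24), CD8 T cells (−0.49), CD4 T cells (−0.43) and regulatory T cells (−0.43). It was negative in 15 of 16 in NK cells (−0.34) and in 14 of 16 in macrophages (−0.15) and mast cells (−0.50). Adjusted p were 8.13e-06, 2.25e-09, 2.67e-09, 1.79e-06, 2.04e-06, 0.00977 and 2.30e-09 in this order, and with an estimated correlation 0.430, 0.197, 0.404, 0.408, 0.240, 0.818 and 0.147. Its leading members were DUSP1 and FOSB in macrophages (−0.39 ± 0.21 and −0.36 ± 0.23), DUSP1 and JUNB in dendritic cells (−0.44 ± 0.18 and −0.31 ± 0.14) and CD8 T cells (−0.76 ± 0.19 and −0.66 ± 0.22). They were ATF3 and DUSP1 in CD4 T cells (−0.57 ± 0.22 and −0.63 ± 0.24) and regulatory T cells (−0.89 ± 0.28 and −0.55 ± 0.22). In the other classes they were JUN and DUSP1 in NK cells (each −0.63 ± 0.24), and BAG3 and JUN in mast cells (−1.31 ± 0.40 and −0.69 ± 0.24). The type I interferon list was higher in 6 classes. In macrophages 20 of 21 were positive (mean 0.38; IFI6 0.62 ± 0.33, HERC5 0.56 ± 0.30), in CD8 T cells 20 of 21 (0.47; RSAD2 0.88 ± 0.34, IFIT1 0.90 ± 0.37), in CD4 T cells 20 of 21 (0.41; OAS1 0.66 ± 0.30, OAS2 0.36 ± 0.17). Positive members numbered 19 of 20 in regulatory T cells (0.29; IRF7 0.45 ± 0.18, IFI6 0.53 ± 0.23), in NK cells 14 of 14 (0.34; IFI6 0.67 ± 0.33, IFI44L 0.81 ± 0.44) and in mast cells 13 of 13 (0.66; IFI44 1.08 ± 0.42, RSAD2 1.46 ± 0.62). Adjusted p were 0.00475, 5.06e-06, 0.00084, 0.00080, 0.00326 and 0.0259, and with an estimated correlation 0.818, 0.340, 0.8292, 0.528, 0.367 and 0.460. The stress call ended in 4 of 20 fits with 1 donor left out in macrophages (adjusted p up to 0.322) and in 0 in the other classes. The interferon call ended in 3 of 20 in macrophages (mean 0.22 to 0.47, up to 0.249), 4 of 19 in mast cells (0.34 to 0.85, 0.177) and 0 in CD8 T cells (0.37 to 0.54), CD4 T cells (0.29 to 0.49), regulatory T cells (0.13 to 0.36) and NK cells (0.28 to 0.42). Macrophages lost the stress call without clusters over 40% in 1 library (−0.08, 0.209). The interferon call ended without shallow libraries in regulatory T cells (0.15, 0.116) and NK cells (0.32, 0.0503), and with the marker gate in NK cells (0.29, 0.0892). In dendritic cells its mean was −0.03 (adjusted p 0.984).

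CD8 T cells of SCC had lower values of XCL1, which encodes a chemokine for XCR1-bearing dendritic cells. XCL1 had −1.45 ± 0.26 (adjusted p 0.0581; called by DESeq2 at 4.85e-05), with 410 ± 168 CPM in IC_BCC, 689 ± 365 in IS_BCC, 252 ± 37.6 in IC_SCC and 172 ± 111 in IS_SCC. It lies on chromosome 1, 168576473 to 168582077, plus strand (ENSG00000143184), beside its paralog XCL2. Calcineurin-NFAT targets were lower in CD8 T cells in 17 of 19 members, mean −0.49 (XCL1 and NR4A1 −0.87 ± 0.21), with 3 lower adjusted over the list alone. They were also lower in CD4 T cells (14 of 21, −0.24; NR4A1 −0.79 ± 0.27, CRTAM −1.09 ± 0.45), regulatory T cells (11 of 16, −0.33; IFNG −1.61 ± 0.49, NR4A1 −0.73 ± 0.22; 5 lower and 1 higher adjusted over the list alone), NK cells (12 of 16, −0.31; XCL1 −0.78 ± 0.26, NR4A1 −0.68 ± 0.25) and mast cells (7 of 10, −0.40; TNF −1.04 ± 0.36, XCL1 −1.57 ± 0.71). Adjusted p were 6.79e-08, 0.00084, 0.00487, 0.00012 and 0.0316, and with an estimated correlation 0.197, 0.790, 0.408, 0.258 and 0.405. The NFAT call ended in 1 of 20 such fits in regulatory T cells (adjusted p up to 0.134), in 9 of 19 in mast cells (0.163) and in 0 in the other classes. Mast cells also lost it with the marker gate (−0.22, 0.0828) and without shallow libraries (−0.11, 0.231). T-cell transcripts were lower in mast cells too (4 of 4, −1.14, adjusted p 0.0960; CD2 −1.43 ± 0.59, CD3G −1.22 ± 0.69), so RNA of T cells is not excluded there, XCL1 included. The NFAT list shares EGR1 with the stress list.

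Cytotoxic genes were higher in SCC in CD8 T cells, with 16 of 17 positive and a mean of 0.22 (PRF1 0.45 ± 0.16, GZMH 0.67 ± 0.24). In NK cells 13 of 16 were positive, mean 0.25 (PRF1 0.46 ± 0.15, GZMB 0.98 ± 0.37), at adjusted p of 0.00256 and 0.00050 (0.197 and 0.240 with an estimated correlation). NK cells also had higher exhaustion genes (9 of 11, 0.32; LAG3 1.40 ± 0.53, while MIR155HG had −0.77 ± 0.34) and lower naive and central memory genes (9 of 11, −0.22; CCR7 −0.99 ± 0.39). These had adjusted p of 0.0156 and 0.00469 (0.240 and 0.258), in a class where 37.36% of cells had CD3E and 9.41% MS4A1, so cells or RNA of other types are not excluded. CD4 T cells had higher exhaustion genes (12 of 15, 0.43; HAVCR2 1.09 ± 0.42, PDCD1 0.54 ± 0.23) and proliferation genes (17 of 19, 0.28; TYMS 0.87 ± 0.43, MCM5 0.51 ± 0.27), and lower mitochondrially encoded transcripts (12 of 13, −0.16; MT-ND4 −0.28 ± 0.16, MT-ND2 −0.31 ± 0.21). These had adjusted p of 0.00084, 0.00960 and 0.0220 (0.790, 0.8292 and 0.8292). A cluster led by CXCL13 was 13.06% and 13.10% of the class in IC_SCC and IS_SCC against 8.47% and 11.55% in BCC, and the T and NK cluster led by cell-cycle genes, left unnamed, is not in the class. Regulatory T cells had higher activation genes (13 of 14, 0.22; FOXP3 0.26 ± 0.10, TNFRSF4 0.53 ± 0.20) and lower glucocorticoid response genes (12 of 16, −0.21; ERRFI1 −0.67 ± 0.22, DUSP1), at adjusted p of 0.00084 and 0.0120 (0.408 for both). In CD8 T cells the hypoxia list (14 of 17, −0.25; HILPDA −0.94 ± 0.35, VEGFA −0.95 ± 0.36), the glucocorticoid list (12 of 15, −0.23; DUSP1, SGK1 −0.76 ± 0.29; 1 lower adjusted over the list alone) and mitochondrially encoded transcripts (13 of 13, −0.19; MT-ND4 −0.34 ± 0.14, MT-ND2 −0.31 ± 0.16) were lower, at adjusted p of 0.00256, 0.00451 and 0.00128 (0.472, 0.340 and 0.472). With 1 donor left out, calls ended in 3 of 19 fits for exhaustion (adjusted p up to 0.1) and 1 of 19 for naive genes (0.112) in NK cells. In CD4 T cells they ended in 3 of 20 for proliferation (0.0704) and 7 of 20 for the mitochondrial list (0.381). They ended in 1 of 20 each for activation (0.119) and glucocorticoid genes (0.103) in regulatory T cells, and for cytotoxicity (0.0514), hypoxia (0.263), glucocorticoid (0.111) and mitochondrial transcripts (0.0677) in CD8 T cells. The exhaustion call of NK cells also ended with doublets kept (0.14, adjusted p 0.184), the marker gate (0.26, 0.164) and without shallow libraries (0.11, 0.390), and their naive call with the marker gate (−0.03, 0.784) and without shallow libraries (−0.17, 0.0503). Proliferation in CD4 T cells ended without shallow libraries (0.21, 0.102).

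Macrophages of SCC had lower presentation genes, and mast cells higher proliferation genes, again with the preset correlation alone. The MHC class II list was negative in 11 of 12 in macrophages, mean −0.21 (HLA-DMA −0.27 ± 0.13, HLA-DOA −0.35 ± 0.18). The MHC class I list was negative in 12 of 13, −0.13 (HLA-B −0.43 ± 0.19), and the interferon-gamma list in 14 of 17, −0.26 (CXCL9 −1.11 ± 0.55, IRF1 −0.43 ± 0.29). In this order they had adjusted p of 2.49e-06, 0.00475 and 0.00475 (0.818 for each with an estimated correlation). Dendritic cells had lower inflammatory cytokines (14 of 17, −0.29; CCL4 −0.97 ± 0.38, CCL3 −0.73 ± 0.36) and higher checkpoint and costimulation ligands (12 of 14, 0.26; CD86 0.48 ± 0.21, HAVCR2 0.27 ± 0.12), at adjusted p of 6.70e-05 and 0.0194 (0.430 for both). Their mixture differed: a cluster led by LIMCH1 and CCL22 was 15.94% and 18.84% of the class in IC_SCC and IS_SCC against 11.96% and 13.31% in BCC, and one led by FCGBP and CD207 was 12.27% in IS_SCC and about 4% elsewhere. In mast cells the proliferation list was positive in 12 of 13, mean 0.82 (TOP2A 1.58 ± 0.50, UBE2C 1.86 ± 0.65; 3 higher adjusted over the list alone), and the MHC class I list in 11 of 13, 0.30 (PSMB10 0.55 ± 0.23, PSMB8 0.59 ± 0.24), while mTORC1 and sterol targets (9 of 11, −0.26; INSIG1 −0.83 ± 0.31) and mitochondrially encoded transcripts (13 of 13, −0.19; MT-ND2 −0.76 ± 0.28, MT-ND1 −0.26 ± 0.22) were lower. Their adjusted p were 4.14e-08, 0.0316, 0.0348 and 0.0259 (0.147, 0.476, 0.405 and 0.481 with an estimated correlation). Calls ended in 2 of 20 fits with 1 donor left out each for MHC class I (adjusted p up to 0.181) and interferon-gamma (0.302) in macrophages and in 3 of 20 for checkpoint ligands in dendritic cells (0.132). In mast cells they ended in 9, 8 and 6 of 19 for MHC class I (0.172), mTORC1 (0.159) and mitochondrial transcripts (0.281). Without clusters over 40% in 1 library the interferon-gamma call of macrophages ended (−0.11, 0.110), and the mTORC1 call of mast cells ended with the marker gate (−0.26, 0.0748) and without shallow libraries (−0.28, 0.0992). In all, 5 of 23 lists passed in Macrophage, 3 of 18 in cDC, 7 of 17 in CD8_T, 6 of 19 in CD4_T, 5 of 18 in Treg, 6 of 14 in NK and 7 of 12 in Mast with the preset correlation. With an estimated one, 0 passed in each.

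Single genes between SCC and BCC numbered 0 by edgeR in each class, with 529 at an unadjusted p under 0.05 in Macrophage, 716 in cDC, 801 in CD8_T, 749 in CD4_T, 742 in Treg, 330 in NK and 523 in Mast. DESeq2 called BTBD2 in cDC (−0.53), XCL1 in CD8_T and 6 genes in Mast (among them MEG3 −1.66, IFFO2 −1.04, TLR4 1.86, APOC2 1.61 and SRBD1 0.86), and 0 in Macrophage, CD4_T, Treg and NK, with 564, 881, 820 and 367 at an unadjusted p under 0.05. Among the genes closest to passing in mast cells were MEG3 −1.59 ± 0.35, FBH1 1.04 ± 0.22, APOC2 1.66 ± 0.36 and AEBP1 3.26 ± 0.71 (adjusted p 0.116), with IFFO2 −1.01 ± 0.25. The other genes of smallest p, none passing, were PDE7B 2.43 ± 0.51, APPL1 0.57 ± 0.13, OSBPL6 2.44 ± 0.57, MAFK −0.58 ± 0.13, ZFPM1 −0.53 ± 0.12 and TWISTNB −0.74 ± 0.18 in regulatory T cells (adjusted p 0.346 to 0.373). They were PDE7B 2.15, ATP8B4 2.92, SH2D2A 0.67, EGR4 −1.75, TLCD2 −1.38 and SOX13 −0.95 in CD4 T cells. In CD8 T cells they were PSMA1 0.38, ABI3 0.66, TRIM5 0.49, CACNA1D −0.90 and PHLDB3 −0.89, and in NK cells SH2D2A 0.92, MAP3K14 0.81, ITGA1 1.84, NFKBIA −0.95, MACO1 −0.66 and HECA −0.71. Macrophages had ZNF148 0.32, CLEC4G 1.46, UBE4B 0.33, SEPTIN1 −0.78, UBD −1.56 and CTNNA3 −2.68, and dendritic cells IGKC 2.93, CRELD2 0.44, ARAP2 0.91, BTBD2 −0.53, DRAIC −1.49 and HECA −0.46. The value of IGKC, an antibody light chain gene, rests on 1 IC_SCC donor, with −0.50 to 3.28 when donors were left out in turn.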

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

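The donors below were singled out by a test that compares the gap of the highest or lowest donor of a group to its nearest neighbour with the range of the group. It was applied to 111 groups of 4 to 9 donors and singled out 18, while chance gives about 1 in 20 groups, and no explanation was tested for them. All of these tests were planned.

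Shares of immune cells lay far above the rest of the group in 9 cases. For macrophages, one IC_SCC donor had 47.5% against 4.95% to 8.17% in the other 3, and one IS_SCC donor 81.3% against 8.79% to 35.6% in the other 8. For plasmacytoid dendritic cells, one IC_SCC donor had 1.2% (others 0% to 0.163%) and one IS_SCC donor 1.27% (0% to 0.352%). One IC_BCC donor had 49.9% CD8 T cells (6.64% to 25.8%), and one IS_SCC donor 18.4% B cells (0.101% to 6.34%). Plasma cells reached 2.09% in one IC_BCC donor (0% to 0.572%), 1.79% in one IC_SCC donor (0% to 0.298%) and 3.28% in one IS_SCC donor (0% to 1.22%).

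Levels of key genes in macrophages stood apart in another 9 cases. APOE had 2078 CPM in one IC_SCC donor against 13.8 to 116 CPM in the other 3. In IS_SCC, one donor each was highest for TREM2 with 345 CPM (others 26.4 to 171), MRC1 with 1098 CPM (128.0 to 583), TNF with 575 CPM (18.3 to 204) and TSC22D3 with 400.3 CPM (82.8 to 183). In IS_BCC, TNF had 306 CPM in one donor (19.9 to 102) and VCAN 423 CPM in one donor (43.0 to 235). In IC_BCC, HLA-DRA had 6044 CPM in the lowest donor (9557 to 11892) and CXCL9 2429 CPM in the highest (69.7 to 717).

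The effect of immune status differed between the tumour types for 1 gene by the test of the difference itself, SLC35E2A in regulatory T cells, with a difference of −1.67. With other splits of the donors, 3 of 50 gave as many genes (1, and at most 1 in another split), so chance is not excluded.

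A signal outside the comparisons came from 544 fibroblast-like cells, which a sort on CD45 should have removed and which were left out.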

How the results depend on the processing

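The settings without shallow libraries (4 libraries with a median under 2000 UMIs), without clusters that had over 40% of their cells in 1 library, and with an unnamed CD8A cluster counted as CD8_T were chosen only after the data were seen, as were all values of the respiratory-chain list. Of the gene counts, 384 of 423 stayed at the same value or within 1.5 times of it, and for the number of gene lists that passed this held for 48 of 74. Among values of named genes, 4434 of 4529 kept their direction and their side of the threshold, 54 passed only under an alternative, 5 passed only in the reported analysis and 36 changed direction. Among values of called lists, 226 of 321 kept both and 91 lost the call in the same direction, while 4 changed direction. Of 150 shares of immune cells, 17 changed direction and none passed. No paired analysis was possible because each donor belongs to 1 group. The median fold change over all genes stayed between −0.043 and 0.0672 in the reported analysis and moved by over 0.1 in 1 setting, no filter on low counts (−0.106 to 0.376). Unless a reason is given, the cause was not tested.

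Counts of genes changed as follows, against 0 in the reported analysis except for 1 in the Treg difference. With the DESeq2 Wald test they were 2 for IS against IC in Macrophage. Within SCC they were 4 in Macrophage, 1 in CD8_T, 1 in Treg and 4 in Mast, and within BCC 1 in Treg and 1 in Mast. For the difference of the effects they were 4 in CD4_T and 2 in Treg, and for SCC against BCC 1 in cDC, 1 in CD8_T and 6 in Mast. The report names these genes except 1 of the 6 in Mast. With no filter on low counts, where more genes of few counts are tested, they were 2 (MARCO and IGFBP2) in Macrophage, 3 in NK and 8 in Mast for IS against IC. There were 10 in NK and 10 in Mast within BCC and 1 in Macrophage, 1 in CD8_T, 3 in NK and 67 in Mast within SCC. There were 1 in CD8_T, 0 in Treg, 1 in NK and 12 in Mast for the difference, and 1 in cDC, 1 in CD8_T (XCL1), 2 in NK (SH2D2A and ITGA1) and 18 in Mast for SCC against BCC. Without the cohort term there was 1 within SCC in cDC (IGHA1). With cohort 1 only, with fewer donors, there was 1 in CD8_T within SCC (CD38) and 0 for the Treg difference. The largest library per donor gave 1 in CD4_T (POMC) and 0 in Treg for the difference and 3 in Mast within SCC (CTSS, RNPEP and AP000676.5). The stricter cell filter gave 1 in Mast within SCC (AP000676.5), the median UMI covariate 0 for the Treg difference, and dropping shallow libraries 0 for it and 1 in CD8_T for SCC against BCC (XCL1). SLC35E2A kept its call with RLE scaling, DESeq2, no cohort term, at least 50 cells, doublets kept, the stricter cell filter and the marker gate.

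RLE scaling, other filters, the largest library and the UMI covariate were not run on fixed lists. With a correlation estimated from each list, numbers of passing lists fell to 0 in each class for IS against IC and SCC against BCC. For IS against IC without the cohort term they were 9 in Macrophage, 0 in cDC, 4 in CD4_T, 1 in NK and 0 in Mast, and with the marker gate 4 in CD4_T and 1 in NK. Without shallow libraries they were 0 in Treg and 0 in Mast for IS against IC and 3 in NK for SCC against BCC. Dropping clusters with over 40% in 1 library gave 5 in Macrophage, and doublets kept 6 in cDC for SCC against BCC.

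Without the cohort term, called lists of IS against IC changed direction for inflammatory cytokines in Macrophage (0.12), and for MHC class II (0.091) and hypoxia (0.20) in cDC. They lost the call for cytokines in cDC (−0.01), interferon-gamma in CD8_T (0.11), type I interferon in Treg (0.27), NK (0.21) and Mast (0.54), myeloid transcripts in Treg (0.59) and NFAT targets in NK (−0.11). Without shallow libraries hypoxia in cDC changed direction (0.040), and the interferon list lost the call in Macrophage (0.49, adjusted p 0.0780), Treg (0.34, 0.0686), NK (0.19, 0.672) and Mast (0.92, 0.063), as did mitochondrial transcripts in Treg (−0.10). The marker gate ended the calls of phagocytosis in Macrophage (0.23, 0.0501) and of interferon (0.13, 0.487) and NFAT targets (−0.43, 0.139) in NK, and dropping clusters over 40% in 1 library that of phagocytosis (0.18, 0.0792). For SCC against BCC, dropping these clusters ended the calls of interferon-gamma (−0.11) and stress (−0.08) in Macrophage. Shallow libraries left out ended those of proliferation in CD4_T (0.21), interferon in Treg (0.15) and NK (0.32), exhaustion (0.11) and naive genes (−0.17) in NK, and NFAT targets (−0.11) and mTORC1 targets (−0.28) in Mast. The marker gate ended interferon (0.29), exhaustion (0.26) and naive genes (−0.03) in NK and NFAT (−0.22) and mTORC1 targets (−0.26) in Mast, and doublets kept ended exhaustion in NK (0.14). In SCC against BCC, the stress list outside Macrophage and the NFAT list of CD8_T, CD4_T, Treg and NK kept their calls. Exceptions among the settings run on lists were the estimated correlation and, for Treg NFAT, 1 donor left out.

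Single genes changed direction for IS against IC, none of them past the threshold. Without the cohort term they were SLCO5A1 0.22, TSC22D3 −0.027 and VCAN −0.21 in Macrophage, and LAG3 0.22, HAVCR2 0.29, CXCL13 0.66 and IL2RA 0.38 in CD8_T. They were also PDCD1 0.046 in CD4_T, IFNG 0.14, GZMB 0.027 and TCF7 0.061 in NK, and HLA-DQA1 0.017, HLA-DRA 0.0049, PFKFB3 0.071 and VEGFA 0.085 in cDC. With cohort 1 only they were TNF −0.044 and TSC22D3 −0.012 in Macrophage and IFNG −0.0090 in CD8_T. Dropping clusters over 40% in 1 library gave SPP1 −0.71 and TNF −0.29 in Macrophage. The median UMI covariate gave TSC22D3 −0.084 and VCAN −0.028 in Macrophage, LAG3 0.0062 in CD8_T and GZMB −0.072 in Treg, and without shallow libraries LAG3 was 0.028 and HAVCR2 0.097 in CD8_T and FKBP5 0.0015 in NK. Counting the CD8A cluster gave IL2RA 0.39 in CD8_T. Doublets kept gave IFNG 0.0019 in CD4_T and FKBP5 0.023 in NK. DESeq2 gave FKBP5 0.018 in NK, no filter on low counts IFNG 0.021 in CD4_T, at least 50 cells LAG3 −0.20 in NK, and the largest library per donor IFNG 0.12, PDCD1 0.047 and CTLA4 −0.0076 in CD4_T.

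Shares beyond the mean over splits, in percent, changed direction for IS against IC with all 30 donors in Macrophage (2.6), pDC (0.0448), CD8_T (−5.56), Treg (−1.72) and Plasma (0.0271), and without shallow libraries in Macrophage (1.56), Mast (−0.158) and CD8_T (−2.62). CD8_T was also negative with doublets kept (−0.227), the largest library per donor (−0.218) and the CD8A cluster (−0.490). On the log2 scale they were 0.219 in Macrophage, −0.141 in cDC, −0.0883 in Mast, −0.0867 in CD8_T and −0.187 in B, and for SCC against BCC −0.0266 in Treg.

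With 1 donor of cohort 1 left out in turn (20 fits, or 19 in NK and Mast), gene counts ran from 0 to 3 in Macrophage and 0 to 1 in Mast for IS against IC, within BCC 0 to 1 in CD8_T and within SCC 0 to 6 in Mast. For the difference they ran from 0 to 1 in CD4_T and 0 to 2 in Treg, and for SCC against BCC 0 to 1 in CD8_T, 0 to 1 in Treg and 0 to 2 in Mast. Lists that passed ran from 2 to 6 in Macrophage, 2 to 6 in cDC, 3 to 6 in CD8_T, 2 to 5 in CD4_T, 1 to 6 in Treg, 0 to 4 in NK and 0 to 2 in Mast for IS against IC. For SCC against BCC they ran from 3 to 7 in Macrophage, 2 to 6 in cDC and 2 to 9 in Mast. The mean of cytokines in Macrophage for IS against IC ran from −0.43 to 0.051. Called lists kept the call in 1064 of 1184 such fits, and the report gives the rest. The mean of 40 of 60 called lists moved by over 1.5 times in at least 1 fit (to a smaller value in 37 and a larger one in 15). Single genes of IS against IC with both directions were SPP1 −0.60 to 0.80, TNF −0.45 to 0.33, TSC22D3 −0.18 to 0.17 and VCAN −0.17 to 0.34 in Macrophage, and IGHA1 −6.09 to 0.44 in cDC (within SCC −8.94 to 2.47). In CD8_T they were IFNG −0.070 to 0.29, GZMB −0.077 to 0.69, PRF1 −0.042 to 0.14, LAG3 −0.15 to 0.085, HAVCR2 −0.32 to 0.060 and FKBP5 −0.29 to 0.23. CD4_T had IFNG −0.28 to 0.23, CTLA4 −0.35 to 0.20, LAG3 −0.30 to 0.35, HAVCR2 −0.33 to 0.38 and TIGIT −0.31 to 0.30, and Treg GZMB −0.34 to 0.57, PRF1 −0.055 to 0.19 and HAVCR2 −0.12 to 0.44. NK had GZMB −0.49 to 0.33, LAG3 −0.026 to 0.60, TCF7 −0.34 to 0.098, IL2RA −1.04 to 0.091 and FKBP5 −0.80 to 0.15. Within SCC, KCNJ6 had −4.95 to 0.37 in CD4_T and GNG4 −3.78 to 0.81 in NK, SYN3 had −5.79 to 0.70 for the difference in Macrophage, and IGKC −0.50 to 3.28 in cDC for SCC against BCC. Shares of IS against IC ran from −1.96 to 3.29 in Macrophage, −3.21 to 2.6 in cDC, −0.120 to 0.0288 in pDC, −0.853 to 0.701 in Mast, −2.25 to 2.90 in CD8_T, −3.69 to 0.391 in CD4_T and −0.778 to 2.14 in Treg. For SCC against BCC they ran from −0.0024 to 0.122 in pDC, −0.119 to 3.19 in CD8_T, −0.266 to 1.56 in Treg and −0.165 to 0.521 in NK.

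Genes past the count filter ran from 7808 in NK and 8387 in Mast to 15312 in cDC. At the real depth and spread, 56 to 73 of 100 simulated changes of 1 on the log2 scale were recovered, and what depth alone limits was not tested.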

Other observations

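In macrophages of IS tumours, nuclear genes of the mitochondrial respiratory chain were shifted together to higher values. Of 75 genes of complexes I to V, 73 had a positive fold change against IC, with a mean of 0.29 and a median of 0.28. Adjusted over the list alone, 13 passed. The adjusted p over classes was 5.26e-30 with the preset correlation, and 0.05002, not passing, with an estimated one. CD8 T cells had 70 of 75 positive (mean 0.17, adjusted p 3.95e-19, and also 0.05002 with an estimated correlation). The mean was 0.11 in CD4 T cells, 0.10 in NK cells, 0.07 in conventional dendritic cells, 0.05 in regulatory T cells and 0.04 in mast cells, and a difference between classes was not tested. For SCC against BCC the mean in macrophages was −0.03, with 30 of 75 positive. Mitochondrially encoded transcripts, which serve the same complexes, were positive in 12 of 13 in macrophages and did not pass (mean 0.15, adjusted p 0.149). In CD8 T cells they went the other way, negative in 13 of 13 (mean −0.23, adjusted p 0.00049, and 0.576 with an estimated correlation), and they are also a sign of cell quality. The respiratory-chain, heat-shock and shortened NFAT lists were chosen after the data were seen, so their adjusted p cannot be compared with the fixed lists. Chosen then too were the 40% cluster setting and the test of myeloid RNA by its share.

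Heat-shock genes had 7 of 7 members lower in SCC than in BCC in 6 classes, with the preset correlation past the threshold and with an estimated one in none. Their means and adjusted p with the 2 correlations were −0.16 (0.0265, 0.424) in conventional dendritic cells, −0.35 (0.00861, 0.415) in CD8 T cells, −0.29 (0.00182, 0.415) in CD4 T cells and −0.31 (0.0206, 0.415) in regulatory T cells. They were −0.27 (0.00483, 0.415) in NK cells and −0.76 (4.16e-08, 0.0949) in mast cells. In macrophages 6 of 7 were lower and the list did not pass (−0.11, adjusted p 0.118). In regulatory T cells they were higher in IS than in IC in 7 of 7 (0.41, adjusted p 0.000614, and 0.678 with an estimated correlation). Without its immediate-early genes, the NFAT list was lower in SCC in CD8 T cells (10 of 12 negative, −0.42, adjusted p 0.00308, estimated 0.296). It was lower in IS in NK cells (9 of 9, −0.55, adjusted p 0.00931, estimated 0.699).

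For the respiratory chain in macrophages, the tables argue against one donor and sequencing depth. Short, abundant transcripts as a whole moved less: 10000 random lists matched for length and level had medians of at most 0.147, against 0.284. The mean stayed at 0.236 or more when any donor of cohort 1 was left out, and was 0.241 (spread 0.0775) with sequencing depth as a covariate. Of 50 splits of the donors, 2 gave as small a p in macrophages (7.52e-31, smallest other 7.91e-34) and 1 in CD8 T cells (1.13e-19, smallest other 1.89e-18). Since the list was chosen on the same data, these splits do not exclude chance and the random lists do not decide on short transcripts. A higher demand for oxidative metabolism in IS macrophages stays open and was not tested.

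For MARCO in IS macrophages, the tables argue against one donor as the cause, since the fold change was at least 1.89 (SE 0.388, adjusted p 0.441) when each was left out. It was 2.07 (SE 0.390, adjusted p 0.133) with the marker gate, but other myeloid cells can pass it, so other cell types stay open. Over all alternatives its adjusted p ran from 0.00077 to 0.892. Clusters drawn largely from 1 library stay open: without them the fold change was 1.24 (SE 0.311, adjusted p 0.892), smaller than 2.07 but above 0 by more than its spread. A response of macrophages to the immune state of the patient may also apply and was not tested.

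For the type I interferon list, higher in IS in 6 classes with the preset correlation and in none with an estimated one (adjusted p 0.543 to 0.930), one donor may account for a large part: when 1 cohort 1 donor was left out, the list kept its call in 2 of the 6 classes, while leaving out any other kept it in 4 or more. RNA of myeloid cells is argued against in CD4 T cells: the rise of the 21 genes would need a median of 23.8% of macrophage RNA, 60.6 times (quartiles 39.4 to 80.9) the 0.393% that 8 myeloid transcripts show. This test replaced the marker gate, which left the myeloid list as shifted (0.597) as the interferon list (0.628) and so decides nothing. Other splits gave as small a p in 22 of 50 in Macrophage (7.14e-05, smallest other 2.98e-17), 10 in CD8_T (2.28e-06, 8.24e-14), 7 in CD4_T (8.50e-08, 8.07e-13), 15 in Treg (0.000158, 2.31e-21), 11 in NK (0.00405, 4.20e-07), 12 in Mast (6.31e-05, 8.46e-13) and 26 in cDC (0.0402, 7.47e-14). Chance is excluded in none of them, and an effect of immune status stays open, untested.

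Other splits of the donors within tumour type, or within immune status and cohort, were fitted 50 times per class with the real one included. For the 34 gene counts of 0, all 50 splits gave as many, and the highest other split gave 0 to 597 genes, with no gene in any other split for 9 of them. Genes at an unadjusted p under 0.05 between IS and IC were as many in 15 splits in Macrophage (929, highest other 2187), 17 in cDC (821, 3017), 27 in CD8_T (427, 2712), 33 in CD4_T (385, 1915), 41 in Treg (254, 1159), 30 in NK (223, 1159) and 14 in Mast (357, 693). Between SCC and BCC they were as many in 28 in Macrophage (529, 3525), 18 in cDC (716, 3754), 11 in CD8_T (801, 1890), 12 in CD4_T (749, 1280), 22 in NK (330, 1285) and 5 in Mast (523, 630). In Treg they were as many in 2 (742, 811), a share under 0.05, as in no other class. With 50 splits per class and no correction over the comparisons, this does not exclude chance. Other splits that call many more genes than the real one point to a structure of the samples, and what it is was not tested.

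Gene lists passing between IS and IC were as many in 48 splits in Macrophage (3, highest other 15), 48 in cDC (3, 15), 24 in CD8_T (5, 10), 46 in CD4_T (2, 13), 33 in Treg (3, 12), 38 in NK (2, 9) and 45 in Mast (1, 9). Between SCC and BCC, in the same order of classes, they were as many in 32 (5, 15), 41 (3, 12), 8 (7, 11), 18 (6, 12), 13 (5, 10), 10 (6, 10) and 4 (7, 9). Chance is excluded in none of these. The stress list for SCC against BCC had as small a p in 1 split in cDC (4.51e-07, smallest other 4.88e-06), 1 in CD8_T (1.32e-10, 2.02e-10) and 2 in CD4_T (1.40e-10, 1.52e-11), a share under 0.05. With 50 splits per class and no correction over the classes, this does not exclude chance. The share was above 0.05 in the others, with 13 in Macrophage (0.00212, 8.37e-09), 6 in Treg (9.96e-08, 1.86e-10), 3 in NK (1.46e-07, 1.49e-16) and 3 in Mast (1.92e-10, 8.48e-13). The respiratory chain for IS against IC had as small a p in 13 in cDC (0.000412, 1.51e-16), 9 in CD4_T (9.32e-07, 5.91e-17), 23 in Treg (0.00121, 4.85e-13), 9 in NK (0.000461, 4.11e-09) and 34 in Mast (0.233, 2.91e-08), where chance is not excluded.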
